A study of Mus musculus with 37 samples.

How the data were processed

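RNA of mouse embryos, MII oocytes and tail tip fibroblasts was measured on single-colour bead arrays of a pair of versions, 22 arrays of the first and 15 of the second, on 8 slides. Per the labels' protocols, RNA was isolated with a PicoPure kit and amplified with biotin labelling by the Illumina TotalPrep kit, and embryos were cultured in KSOM. Per the labels, 2-cell controls, cleavage-inhibited and zygote NT embryos were taken, where a time is given, 22 to 24 h after the start, blastomere NT embryos and 4-cell controls 14 h after transfer or release from a mitotic block, and oocyte NT embryos and the parthenote after 2 d. How many embryos were pooled per array, and their sex, was not given in the sources used here.

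The deposited tables held, per the file headers and the labels, an average bead intensity for every probe and array from GenomeStudio (version not given), not normalized between arrays. A detection p-value for every probe and array stood beside it, as deposited by the authors. The deposited series matrix held intensities of 16075 probes on a linear scale with values below 0; no label states how they were made. Each matrix column was a straight-line transform of its unnormalized column, with background subtracted and 1 scale factor per array, except the repeat hybridization of a cleavage-inhibited sample (r = 0.996). Column medians lay between 3.08 and 19.5 on the first version and between 4.39 and 12.0 on the second. The 75th percentile of the unnormalized signal lay between 23.5 and 152, and between 203 and 537.

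Each array version was normalized on its own with neqc of limma 3.58.1 in R 4.3.3. Normexp background correction took its negative controls from the detection p-values, with an offset of 16, and quantile normalization and log2 followed. Levels compared across versions therefore come from tables normalized separately. Probes detected at p below 0.0500 on at least 2 arrays were kept. Of 24613 and 25697 probes, 14898 and 15052 had 1 symbol in the platform table, 9715 and 10645 had none and 0 had several; 14890 and 15043 were matched to the reference by gene identifier. The brightest probe stood for a gene, which left 8141 and 7173 genes. The lowest signal called detected ranged over arrays from 4.48 to 6.56 and from 5.78 to 6.58 log2.

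Groups followed the labels. The title and description of 4-cell control 2 name different slides, and that of the description was used because the other position is taken by an oocyte NT array. Repeat hybridizations were left out of the first version's fit, since they held RNA already present there; the labels name their group but not their partner, which was taken as the best-correlated sample of the group. Blastomere NT arrays 1 and 3 were averaged as 1 sample. One group-means model per version was fitted to 19 and 14 samples with 10 and 5 residual degrees of freedom, with limma's moderated variances (eBayes, trend), and genes passed at a Benjamini-Hochberg adjusted p below 0.0500, two-sided, per comparison. There were 14 comparisons. The 25 gene lists were fibroblast, contractile, 2-cell transient activation, early zygotic genome activation, ribosome biogenesis, ribosomal protein, oocyte and maternal, pluripotency, trophectoderm and primitive endoderm, cumulus and granulosa cell, keratinocyte, macrophage and leukocyte, endothelial, muscle, mitotic, DNA replication, p53 response, DNA methylation and chromatin, imprinted, glycolysis, oxidative phosphorylation, proteasome, spliceosome, interferon response and MHC class I, and immediate early and stress genes. Camera with a preset correlation of 0.010 tested them, with Benjamini-Hochberg adjustment per comparison, beside camera with an estimated correlation and fry.

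The donor set held genes at least 2 log2 higher in fibroblasts than in interphase zygotes, and the activation and decay sets genes at least 1 log2 higher or lower in cleavage-inhibited embryos than in interphase zygotes, all past the adjusted p. Named genes were, in each comparison, the 6 largest rises and falls among genes that passed, had no overlap between groups and were detected on every array of the higher group, up to 3 genes of each list with a call, and a fixed set of 15 markers; genes of this rule were left out for length only. Groups, comparisons, lists, sets, this rule and the alternatives were fixed before the data were examined, apart from the alternatives named as added later.

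The model was tested on simulated data with 100 genes moved by 1 and 100 by 2 log2 per comparison. Of genes moved by 2 log2 it recovered 82% in prometaphase and 81% in anaphase NT against 2-cell controls (8141 genes each). In blastomere NT against 4-cell controls (7173 genes) it was 42%. Of genes moved by 1 log2 it recovered 24, 26 and 1%, with 2.75, 6.96 and 2.27% of calls false. Wider anaphase NT spread was not simulated. Alternatives were no background correction, scaling to a 75th percentile, series matrix values, no detection filter, every probe on its own, averaged repeat hybridizations, a log2 minimum of 1, other set thresholds, a fit of the compared groups alone, slide as a fixed or random block, and leaving out each sample in turn. Added after the data were seen were a fit without the weak arrays, blastomere NT 1 and 3 as separate samples, values within a slide, and list tests under the settings above. Figures were drawn with matplotlib 3.10.9 under python 3.11.15 (numpy 2.4.6, pandas 2.3.3).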

Results

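Gene expression was measured on 37 single-colour bead arrays in mouse embryos whose genome had been exchanged at mitosis, in their recipient cells and in control embryos. Per the labels, tail tip fibroblasts in interphase were the nuclear donors for zygotes at prometaphase or anaphase of mitosis and for MII oocytes, and the design text names fibroblast transfer into blastomeres as well. The first array version held 22 arrays. Tail tip fibroblasts, interphase zygotes and M-phase zygotes had 3 samples each. Another 2 samples each came from 2-cell controls, embryos kept from cleaving until 2-cell timing, anaphase nuclear transfer (NT) embryos and prometaphase NT embryos. Single samples came from embryos without a genome and from interphase NT with embryonic stem (ES) cells, and 3 arrays were repeat hybridizations. The second held 15 arrays, of which 3 came from blastomere NT embryos and 2 each from 4-cell controls, oocyte NT embryos and MII oocytes. It also held 1 parthenote, 1 array each of the genome-less and ES NT samples, and 3 repeat hybridizations of 2-cell and cleavage-inhibited RNA. Blastomere NT replicates 1 and 3 were counted as 1 sample (n = 2 for this group), since they differed about as little as the repeat hybridizations of the first version did from their presumed partners, themselves chosen by best correlation. The standard deviation of their log2 difference across probes was 0.133, against 0.128 to 0.148 in those 3 pairs. Outside the range of the pairs lay r (0.995, against 0.996 to 0.997) and the median absolute difference (0.127, against 0.111 to 0.123).

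Probes were detected at rates of 18.8 to 45.7% per array on the first version and 33.8 to 44.0% on the second. The few samples per group limit the precision of every value. Replicates correlated, across probes, between 0.819 (both anaphase NT samples) and 0.996 (a pair of fibroblast samples). Interphase zygote 1 stood apart from its group (r = 0.907 and 0.902, against 0.968 between the other samples). Labels call many samples biological duplicates but say nothing on separate litters or donors, so p-values measure the spread between these samples, which may in part be technical. Changes are given as log2 differences ± standard error with limma's Benjamini-Hochberg adjusted p. Every named gene that passed had all samples of one group above all of the other. A gene detected on no array of the lower group has only a bound: it is given as "at least N-fold", its higher group's mean against the lowest detected signal. Medians of gene lists are given as fitted and, where they differ, with undetected genes set at that floor, except in the fits by slide and within slides.

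Donor fibroblasts and 2-cell controls, the starting point and the stage-matched reference of the transfers, differed for 4032 of 8141 genes (n = 3 against 2): 2076 were higher and 1956 lower in fibroblasts. Fibroblasts carried the extracellular matrix genes Dcn, a collagen-binding proteoglycan (at least 175-fold higher, adjusted p = 8.01e-12), Col6a1 (at least 236-fold higher) and Fbln2 (at least 207-fold higher). Also higher were smooth muscle actin Acta2 (at least 236-fold higher, adjusted p = 6.09e-12), the surface glycoprotein Thy1 (log2 5.98 ± 0.26, adjusted p = 2.35e-10) and Gas6, a ligand of TAM receptor kinases (at least 264-fold higher). They also carried the macrophage genes Laptm5 (at least 206-fold higher, adjusted p = 5.04e-05) and Adgre1, which encodes the F4/80 antigen (at least 103-fold higher, adjusted p = 6.09e-12). The 2-cell embryos stood above them for Dppa4 (at least 232-fold lower, adjusted p = 6.73e-06), Zscan5b (at least 128-fold lower), Pramel7 (at least 95.7-fold lower), and the alkaline phosphatase gene Alppl2 (at least 109-fold lower). The oocyte gene Oog1 (at least 119-fold lower), the oocyte growth factor Gdf9 (log2 -6.12 ± 0.20) and the transcription factor Klf5 (log2 -4.91 ± 0.48) were lower in fibroblasts as well.

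Fibroblast genes parted the cell types, and macrophage and leukocyte markers stood higher in the donor cells beside them. Of 31 fibroblast genes 30 were higher and 1 did not pass (30 higher adjusted over the list alone). The fibroblast median was 5.98 (5.86 at the floor) log2, with camera adjusted p = 2.26e-20 and adjusted p = 0.00801 with an estimated correlation. Among 20 macrophage and leukocyte genes 17 were higher and 3 did not pass (17 higher adjusted over the list alone), with a median log2 of 3.24 (2.92 at the floor), camera adjusted p = 3.43e-08 and adjusted p = 0.00801 with an estimated correlation. Genes of ribosome biogenesis and of the oocyte stood lower in fibroblasts. Of 44 ribosome biogenesis genes 34 were lower and 10 did not pass (34 lower adjusted over the list alone). Median log2 over ribosome biogenesis genes was -2.34, with camera adjusted p = 1.69e-09 and adjusted p = 0.0147 with an estimated correlation. Among 47 oocyte and maternal genes 33 were lower and 14 did not pass (36 lower adjusted over the list alone), with a median log2 of -2.52 (-2.32 at the floor), camera adjusted p = 3.49e-12 and adjusted p = 0.00801 with an estimated correlation. Matrix values moved the macrophage and oocyte medians to 5.21 and -4.34. Fitted with slide as a block, 1929 genes passed, and the medians of the fibroblast and ribosome biogenesis lists were 5.36 and -2.32. No slide held both groups.

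The normal change over the same cell cycle was taken as 2-cell controls against M-phase zygotes, the recipient stage (n = 2 against 3). It covered 3461 genes, 1672 higher and 1789 lower. Klf5 rose (log2 4.98 ± 0.48), as did nucleolin, Ncl (log2 4.87 ± 0.39), cyclin E1, Ccne1 (log2 5.89 ± 0.33), and Guca1a (log2 7.10 ± 0.32). Further rises were those of Pheta1 (log2 6.88 ± 0.28), Selenos (log2 6.37 ± 0.37), Ppp2cb (log2 6.66 ± 0.99), Pramel7 (at least 87.5-fold higher, adjusted p = 1.04e-07) and Tead4, a transcription factor of the trophectoderm (at least 18.5-fold higher, adjusted p = 8.39e-09). The oocyte growth factors Bmp15 (log2 -5.0 ± 0.38) and Gdf9 (log2 -1.39 ± 0.20), the histone chaperone Npm2 (log2 -2.82 ± 0.29), the germ line gene Tdrd12 (log2 -6.20 ± 0.37), the connexin gene Gja4 (log2 -5.65 ± 0.44), Gpr1 (log2 -5.56 ± 0.38) and the imprint regulator Zfp57 (log2 -5.28 ± 0.35) fell.

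Genes of ribosome biogenesis rose over this cycle, and oocyte genes fell. Of 44 ribosome biogenesis genes 33 were higher, 1 lower and 10 did not pass (33 higher and 2 lower adjusted over the list alone). The ribosome biogenesis median was 2.17 log2, with camera adjusted p = 4.39e-10 and adjusted p = 0.0342 with an estimated correlation. Among 47 oocyte and maternal genes 2 were higher, 34 lower and 11 did not pass (2 higher and 35 lower adjusted over the list alone), with a median log2 of -2.10, camera adjusted p = 2.74e-10 and adjusted p = 0.0342 with an estimated correlation. A fit with slide as a block called 2562 genes, with medians of 2.27 for ribosome biogenesis and -1.76 for oocyte genes. Within slide 3 the same medians were 2.21 and -2.06.

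Anaphase NT embryos against 2-cell controls asked what still differed from the stage-matched embryo (n = 2 against 2). They differed for 2904 genes, 1392 higher and 1512 lower. Fibroblast genes above the control were Thy1 (log2 3.74 ± 0.28, adjusted p = 5.61e-07), Dcn (at least 27.3-fold higher, adjusted p = 1.78e-08), and the secreted serpin Serpinf1 (log2 5.0 ± 0.36, adjusted p = 4.08e-07). Also higher were S100a6, a calcium-binding protein (log2 5.81 ± 1.13), Acta2 (at least 32.3-fold higher, adjusted p = 1.54e-08), the tetraspanin Cd81 (at least 41.6-fold higher, adjusted p = 0.000192) and the membrane skeleton gene Epb41l3 (at least 53.1-fold higher, adjusted p = 1.35e-06). Lower were Dppa4 (log2 -5.73 ± 1.04, adjusted p = 0.000723), Pramel7 (log2 -5.57 ± 0.49), Alppl2 (at least 81.4-fold lower, adjusted p = 8.61e-09), Fmr1nb (at least 27.4-fold lower, adjusted p = 2.04e-07) and Flvcr2 (log2 -5.41 ± 0.29). So were the transcription factors Sox21 (at least 29.4-fold lower, adjusted p = 6.07e-09), Sox15 (log2 -3.45 ± 0.42) and Klf5 (log2 -2.44 ± 0.53, adjusted p = 0.00249). The nuclear receptors Nr5a2 (log2 -3.77 ± 0.51) and Esrrb (log2 -3.46 ± 0.36) and the trophectoderm regulators Tead4 (at least 15.1-fold lower, adjusted p = 1.78e-08) and Tfap2c (at least 14.1-fold lower, adjusted p = 1.28e-07) were lower too. Pou5f1 (log2 0.65 ± 0.41, adjusted p = 0.242) and Nanog (log2 -2.15 ± 0.95, adjusted p = 0.0954), factors of the pluripotency network, did not pass. Without anaphase NT 15, which did not detect it, the log2 difference of Dppa4 was -3.33.

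Maternal transcripts higher in these embryos than in the controls included Bmp15 (log2 3.92 ± 0.42), the deadenylase gene Cnot6l (log2 3.53 ± 0.33), Npm2 (log2 1.40 ± 0.32) and Gdf9 (log2 0.82 ± 0.22; not past the threshold without 2-cell control 23). Dppa3 (log2 -1.15 ± 0.27), also maternal, and the homeobox gene Obox6 (log2 -4.45 ± 0.26) were lower. Zfp352 was higher (log2 3.23 ± 0.48), of the 2-cell activation list, which camera did not call (adjusted p = 0.661). Immediate early genes Ier3 (log2 6.27 ± 0.65, adjusted p = 8.43e-06), Klf6 (log2 4.11 ± 0.49) and Fos (at least 11.9-fold higher, adjusted p = 5.95e-05), the glycolytic enzymes Tpi1 (log2 2.49 ± 0.24) and Gapdh (log2 2.32 ± 0.34), and the imprinted growth factor Igf2 (log2 3.51 ± 0.50) were higher. The ribosome assembly factors Tbl3 (log2 -5.09 ± 0.46) and Nip7 (log2 -4.70 ± 0.71), the mitotic kinase Cdk1 (log2 -3.54 ± 0.72) and the proteasome subunit Psmd13 (log2 -4.08 ± 0.89) were lower. Without anaphase NT 15 Nip7, Cdk1 and Psmd13 stood at log2 -3.0, -1.91 and -2.53.

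Camera called the fibroblast, oocyte and stress lists higher than in 2-cell controls, each lost with an estimated correlation. Of 31 fibroblast genes 19 were higher and 12 did not pass (21 higher adjusted over the list alone). Median log2 over fibroblast genes was 1.63 (1.17 at the floor), with camera adjusted p = 1.47e-08 and adjusted p = 0.0574 with an estimated correlation. Oocyte and maternal genes, 47 in number, split as follows: 28 were higher, 3 lower and 16 did not pass (28 higher and 4 lower adjusted over the list alone). Median log2 over these genes was 1.39 (1.40 at the floor), with camera adjusted p = 6.3e-06 and adjusted p = 0.0574 with an estimated correlation. Of 28 immediate early and stress genes 11 were higher, 1 lower and 16 did not pass (11 higher and 1 lower adjusted over the list alone). The immediate early and stress median was 0.61 (0.64 at the floor) log2, with camera adjusted p = 0.0197 and adjusted p = 0.335 with an estimated correlation. Among lists called lower, ribosome biogenesis and proteasome were kept with an estimated correlation, and ribosomal protein and oxidative phosphorylation were not. Among 44 ribosome biogenesis genes 1 was higher, 32 lower and 11 did not pass (1 higher and 35 lower adjusted over the list alone), with a median log2 of -2.13 (-2.06 at the floor), camera adjusted p = 5.52e-13 and adjusted p = 0.0131 with an estimated correlation. Of 30 ribosomal protein genes 14 were lower and 16 did not pass (14 lower adjusted over the list alone). Median log2 over ribosomal protein genes was -1.01, with camera adjusted p = 0.000616 and adjusted p = 0.377 with an estimated correlation. Among 23 proteasome genes 15 were lower and 8 did not pass (15 lower adjusted over the list alone), with a median log2 of -1.46 (-1.37 at the floor), camera adjusted p = 2.83e-06 and adjusted p = 0.00588 with an estimated correlation. Of 42 oxidative phosphorylation genes 18 were lower and 24 did not pass (20 lower adjusted over the list alone). The oxidative phosphorylation median was -1.20 (-0.97 at the floor) log2, with camera adjusted p = 2.16e-06 and adjusted p = 0.335 with an estimated correlation. Without anaphase NT 19 the fibroblast median was 0.94. Without anaphase NT 15 those of ribosomal protein and oxidative phosphorylation genes were -0.65 and -0.71. Matrix values gave medians of 3.24 (fibroblast) and 1.07 (stress), and 75th percentile scaling -1.61 (ribosomal protein).

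Camera also called the mitotic and pluripotency lists lower, both lost with an estimated correlation. Among 21 mitotic genes 11 were lower and 10 did not pass (12 lower adjusted over the list alone), with a median log2 of -0.91 (-0.86 at the floor), camera adjusted p = 0.000387 and adjusted p = 0.276 with an estimated correlation. Of 21 pluripotency genes 2 were higher, 8 lower and 11 did not pass (2 higher and 8 lower adjusted over the list alone). Median log2 over pluripotency genes was -0.71 (-0.48 at the floor), with camera adjusted p = 0.041 and adjusted p = 0.355 with an estimated correlation. Without anaphase NT 19 the call of the stress list ended, and that of the pluripotency list ended without anaphase NT 15 or 2-cell control 22 and with series matrix values. The pluripotency median was -0.30 without anaphase NT 15 and -1.09 without 19, where the mitotic median was -1.44.

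Anaphase NT samples and 2-cell controls lay on different slides. A model with slide as a block called 893 genes, with medians of 1.61 for fibroblast and -2.09 for ribosome biogenesis genes. On slide 3, which also held a repeat hybridization matching anaphase NT 19, the list medians were 2.49 and -1.87. In a fit of these groups alone 353 genes passed.

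Prometaphase NT embryos differed from the 2-cell controls (n = 2 against 2) for 174 genes, 132 higher and 42 lower. Higher genes included Anxa2, an annexin (log2 3.72 ± 0.33, adjusted p = 3.06e-05), Serpinf1 (log2 3.23 ± 0.36, adjusted p = 0.000278), Thy1 (log2 1.69 ± 0.28, adjusted p = 0.00576) and Acta2 (at least 1.82-fold higher, adjusted p = 0.011). Next to these stood the small heat shock protein Hspb1 (log2 3.74 ± 0.56, adjusted p = 0.00256), Ier3 (log2 3.04 ± 0.65, adjusted p = 0.0264) and the kinesin Kifc2 (at least 6.51-fold higher, adjusted p = 3.94e-05). Other rises were the hormone subunit Gpha2 (at least 5.23-fold higher, adjusted p = 0.000305), the imprinted transporter Slc38a4 (at least 6.26-fold higher, adjusted p = 0.0129), Chit1 (log2 2.26 ± 0.41) and Lefty1 (at least 1.57-fold higher, adjusted p = 0.0329). Pkp3 (log2 1.18 ± 0.26), Gapdh (log2 1.45 ± 0.34) and the MHC class II gene H2-Ab1 (at least 1.78-fold higher, adjusted p = 1.92e-05) were higher as well. Lower were the receptor Notch4 (log2 -2.65 ± 0.29, adjusted p = 0.000217), Fbxo16 (log2 -2.62 ± 0.48), Rpl39l (log2 -2.41 ± 0.56), F8 (at least 3.85-fold lower, adjusted p = 0.00598), Pacsin1 (log2 -2.27 ± 0.40) and Zhx3 (log2 -2.26 ± 0.33). The endothelial adhesion gene Esam (log2 -1.46 ± 0.16), the p53 target Aen (log2 -0.77 ± 0.08) and the maternal gene Tcl1 (log2 -1.20 ± 0.27) were lower too. No call was made for Pou5f1 (log2 -0.41 ± 0.41), Nanog (log2 0.90 ± 0.95), Klf5 (log2 -0.29 ± 0.53), Gdf9 (log2 -0.36 ± 0.22), Npm2 (log2 -0.88 ± 0.32), Dppa3 (log2 -0.21 ± 0.27) or Cdkn1a (log2 0.03 ± 0.34). Pkp3 stood at log2 0.71 without prometaphase NT 28. For the genes without a call adjusted p were 0.246 (Npm2) or higher.

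Fibroblast genes were the only list above the control level in the camera test and oocyte genes the only list below it. Among 31 fibroblast genes 4 were higher and 27 did not pass (5 higher adjusted over the list alone), with a median log2 of 0.12 (-0.02 at the floor), camera adjusted p = 0.00133 and adjusted p = 0.796 with an estimated correlation. The mean of the fibroblast list was 0.53, against a median of the other sign at the floor. Of 47 oocyte and maternal genes 1 was lower and 46 did not pass (5 lower adjusted over the list alone). The oocyte and maternal median was -0.36 (-0.33 at the floor) log2, with camera adjusted p = 8.68e-05 and adjusted p = 0.359 with an estimated correlation. The fibroblast call ended without prometaphase NT 28 and with scaling to a 75th percentile, with medians of 0.04 and -0.16, and it was 0.20 without prometaphase NT 27 and 0.56 with matrix values. All 4 arrays lay on slide 3, and with slide as a block over all groups 115 genes passed. A fit of both groups alone called 1, 75th percentile scaling 49, and the fit without prometaphase NT 27 110. Of the 23 named calls 8 were lost without it, 9 without prometaphase NT 28, 7 without 2-cell control 22 and 8 without 2-cell control 23. Anxa2, Serpinf1, Hspb1, Kifc2, Gpha2, H2-Ab1, Notch4, F8, Zhx3, Esam and Aen were lost in none.

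**Figure D1:**
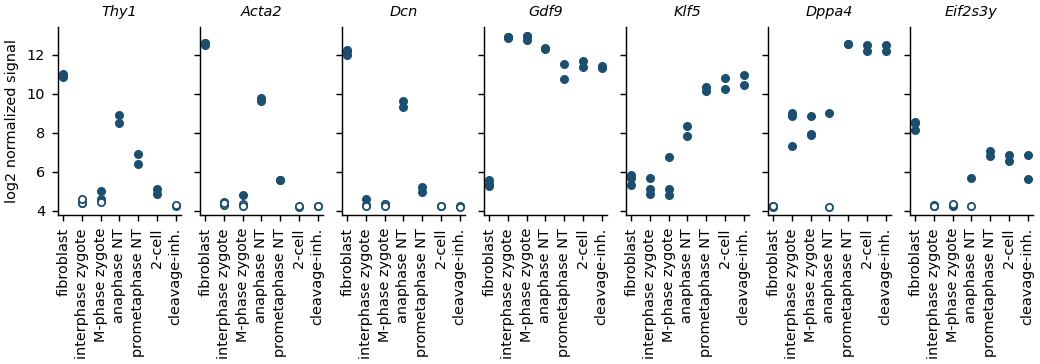
Normalized log2 signal (y axis) of genes named in the text in samples of the first array version, by group (x axis). Points are samples, open where the gene was undetected. Thy1 stands at 8.71 in anaphase NT, 6.66 in prometaphase NT and 4.97 in 2-cell controls.

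A direct contrast of both transfers addressed the mitotic stage of transfer (n = 2 against 2) and gave 3318 genes, 1592 higher and 1726 lower after anaphase transfer. Bmp15 (log2 5.39 ± 0.42, adjusted p = 7.36e-07), Dcn (log2 4.37 ± 0.25, adjusted p = 6.24e-08), Acta2 (log2 4.15 ± 0.25), the gelatinase Mmp2 (log2 4.00 ± 0.36) and Thy1 (log2 2.06 ± 0.28) were higher after anaphase transfer. So were Epb41l3 (log2 5.09 ± 0.48), the cytokine Il7 (log2 4.98 ± 0.52), the Polycomb gene Bmi1 (log2 4.92 ± 0.42), the RNA-binding protein Stau2 (at least 22.8-fold higher, adjusted p = 5.46e-07), Zfp352 (log2 3.39 ± 0.48) and Igf2 (log2 4.03 ± 0.50). Dppa4 (log2 -5.95 ± 1.04, adjusted p = 0.000508), Pramel7 (log2 -5.55 ± 0.49), Alppl2 (at least 59.6-fold lower, adjusted p = 1.43e-08) and Flvcr2 (log2 -6.21 ± 0.29) were lower. Further falls were those of Ankmy2 (log2 -5.51 ± 0.37), Cyp2s1 (at least 40.5-fold lower, adjusted p = 1.81e-07), Klf5 (log2 -2.16 ± 0.53), Tead4 (at least 17.3-fold lower, adjusted p = 1.43e-08), Obox6 (log2 -4.90 ± 0.26), Nip7 (log2 -4.39 ± 0.71) and Cdk1 (log2 -4.02 ± 0.72). Without anaphase NT 15 Dppa4, Nip7 and Cdk1 stood at log2 -3.54, -2.69 and -2.39.

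Camera called the fibroblast (not with an estimated correlation) and oocyte lists higher after anaphase than after prometaphase transfer, and the ribosome biogenesis list lower. Among 31 fibroblast genes 15 were higher and 16 did not pass (16 higher adjusted over the list alone), with a median log2 of 1.12 (1.11 at the floor), camera adjusted p = 1.09e-05 and adjusted p = 0.136 with an estimated correlation. Of 47 oocyte and maternal genes 31 were higher, 4 lower and 12 did not pass (33 higher and 4 lower adjusted over the list alone). Median log2 over oocyte and maternal genes was 1.83, with camera adjusted p = 3.53e-08 and adjusted p = 0.0296 with an estimated correlation. Among 44 ribosome biogenesis genes 1 was higher, 32 lower and 11 did not pass (1 higher and 34 lower adjusted over the list alone), with a median log2 of -2.20 (-1.99 at the floor), camera adjusted p = 1.79e-10 and adjusted p = 0.0274 with an estimated correlation. For fibroblast genes the median was 1.82 without anaphase NT 15, 0.62 without 19 and 1.91 with matrix values. The model with slide as a block called 1021 genes (fibroblast median 1.34, ribosome biogenesis -2.08), and within slide 3 those medians were 1.82 and -1.85. A fit of both groups alone called 890.

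Against the donor cells, anaphase NT embryos (n = 2 against 3) differed for 4461 genes, 2139 higher and 2322 lower. The 2-cell gene Tcstv3 (at least 305-fold higher, adjusted p = 4.26e-12), the oocyte genes Oosp1 (at least 285-fold higher), Oog1 (at least 225-fold higher) and Gdf9 (log2 6.94 ± 0.20), Gdap1 (at least 232-fold higher) and Klf5 (log2 2.47 ± 0.48) were higher than in fibroblasts. Col6a1 (log2 -7.10 ± 0.34), Fbln2 (log2 -6.50 ± 0.60), Gas6 (log2 -6.97 ± 0.42), Srpx2 (log2 -6.44 ± 0.24), the surface protein Thy1 (log2 -2.24 ± 0.26), the platelet factor gene Pf4 (at least 57.4-fold lower) and Adgre1 (at least 88.9-fold lower, adjusted p = 7.14e-12) were lower. Fibroblast and macrophage genes stood below the donor level. Of 31 fibroblast genes 29 were lower and 2 did not pass (1 higher and 29 lower adjusted over the list alone). The fibroblast median was -3.58 (-3.28 at the floor) log2, with camera adjusted p = 1.15e-14 and adjusted p = 0.0172 with an estimated correlation. Among 20 macrophage and leukocyte genes 17 were lower and 3 did not pass (17 lower adjusted over the list alone), with a median log2 of -3.05 (-2.63 at the floor), camera adjusted p = 8.52e-08 and adjusted p = 0.0136 with an estimated correlation. Oocyte and 2-cell activation genes stood higher. Of 47 oocyte and maternal genes 41 were higher and 6 did not pass (42 higher adjusted over the list alone). Median log2 over oocyte and maternal genes was 4.25 (4.03 at the floor), with camera adjusted p = 3.12e-18 and adjusted p = 0.0044 with an estimated correlation. Among 10 2-cell activation genes 7 were higher and 3 did not pass (7 higher adjusted over the list alone), with a median log2 of 4.28 (4.11 at the floor), camera adjusted p = 0.000423 and adjusted p = 0.0457 with an estimated correlation. With matrix values the macrophage and 2-cell activation medians were -5.26 and 6.49. Blocking by slide, 1754 genes passed, with medians of -3.35 and 4.24 for fibroblast and oocyte genes. No slide held both groups.

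Prometaphase NT embryos (n = 2 against 3) differed from the donor for 3822 genes, 1849 higher and 1973 lower. Dppa4 (at least 269-fold higher, adjusted p = 5.42e-06), Zscan5b (at least 126-fold higher), Tcstv3 (at least 103-fold higher), Klf17 (at least 97.4-fold higher), Pramel7 (at least 94.4-fold higher) and Klf5 (log2 4.63 ± 0.48) were higher than in fibroblasts. Gas6 (at least 275-fold lower), Fbln2 (at least 215-fold lower), Col6a1 (log2 -7.94 ± 0.34), the metalloproteinase inhibitor Timp2 (at least 185-fold lower), Igfbp4 (at least 171-fold lower), Adgre1 (at least 107-fold lower) and Thy1 (log2 -4.29 ± 0.26) were lower. Fibroblast and macrophage lists stood lower than in the donor. Of 31 fibroblast genes 30 were lower and 1 did not pass (30 lower adjusted over the list alone). The fibroblast median was -4.80 log2, with camera adjusted p = 6.25e-20 and adjusted p = 0.0107 with an estimated correlation. Among 20 macrophage and leukocyte genes 1 was higher, 16 lower and 3 did not pass (1 higher and 16 lower adjusted over the list alone), with a median log2 of -2.90 (-2.84 at the floor), camera adjusted p = 4.06e-07 and adjusted p = 0.0107 with an estimated correlation. The macrophage median with matrix values was -4.69. Genes of ribosome biogenesis stood higher. Of 44 ribosome biogenesis genes 34 were higher and 10 did not pass (37 higher adjusted over the list alone). Median log2 over ribosome biogenesis genes was 2.12, with camera adjusted p = 2.71e-09 and adjusted p = 0.0158 with an estimated correlation. Blocking by slide, the fit called 1842 genes, and the fibroblast median was -4.64 and that of ribosome biogenesis 2.09. No slide held both groups.

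Relative to the recipient M-phase zygotes, anaphase NT embryos (n = 2 against 3) differed for 3260 genes, 1576 higher and 1684 lower. Tdpoz1 (log2 5.78 ± 0.27) and Zfp352 (log2 4.06 ± 0.44) of the 2-cell activation list, Klf5 (log2 2.53 ± 0.48) and cyclin E1 (log2 3.38 ± 0.33) rose. The circadian factor Dbp (log2 5.37 ± 0.46), Serpinf1 (log2 5.31 ± 0.33), Acta2 (log2 5.26 ± 0.23) and Dcn (at least 28.9-fold higher, adjusted p = 1.08e-08) rose as well. Supt3 (at least 64.3-fold lower, adjusted p = 4.58e-08), Nudt16l1 (at least 44.6-fold lower, adjusted p = 1.56e-07), Elp3 (log2 -5.71 ± 0.63), Gpr1 (log2 -5.61 ± 0.38), Zfp57 (log2 -4.03 ± 0.35), Aurora kinase A, Aurka (log2 -3.84 ± 0.29), and Npm2 (log2 -1.43 ± 0.29) fell. Camera called the fibroblast and 2-cell activation lists higher, and the oocyte list lower, but none with an estimated correlation. The second call ended without anaphase NT 19. Among 31 fibroblast genes 20 were higher and 11 did not pass (21 higher adjusted over the list alone), with a median log2 of 1.23 (1.12 at the floor), camera adjusted p = 7.15e-07 and adjusted p = 0.288 with an estimated correlation. Of 10 2-cell activation genes 5 were higher, 2 lower and 3 did not pass (6 higher and 2 lower adjusted over the list alone). The 2-cell activation median was 1.74 (1.80 at the floor) log2, with camera adjusted p = 0.0188 and adjusted p = 0.288 with an estimated correlation. Fibroblast genes had a median of 1.89 without anaphase NT 15 and 2.27 with matrix values, and that of the 2-cell activation list 2.62 without 15 and 0.87 without 19. Among 47 oocyte and maternal genes 1 was higher, 24 lower and 22 did not pass (1 higher and 25 lower adjusted over the list alone), with a median log2 of -0.73 (-0.65 at the floor), camera adjusted p = 0.000519 and adjusted p = 0.288 with an estimated correlation. The fit blocked by slide called 1948 genes (fibroblast median 1.22, oocyte -0.96), and a fit of both groups alone 2137. Within slides 2 and 3 the fibroblast medians were 1.20 and 1.76 and the oocyte medians -0.96 and -1.04.

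Prometaphase NT embryos against the same zygotes (n = 2 against 3) gave 3673 genes, 1873 higher and 1800 lower. Pheta1 (log2 7.39 ± 0.28), Guca1a (log2 6.79 ± 0.32), Selenos (log2 6.69 ± 0.37), cyclin E1 (log2 5.85 ± 0.33), Obox6 (log2 5.37 ± 0.24), Klf5 (log2 4.69 ± 0.48), Pramel7 (at least 86.3-fold higher, adjusted p = 8.31e-08) and Tead4 (at least 21.3-fold higher, adjusted p = 4.94e-09) rose. Bmp15 (log2 -6.46 ± 0.38), Tdrd12 (log2 -6.29 ± 0.37), Slc4a8 (log2 -6.32 ± 0.58), Gpr1 (at least 53.9-fold lower, adjusted p = 4.77e-08), Npm2 (log2 -3.70 ± 0.29) and Gdf9 (log2 -1.76 ± 0.20) fell. Ribosome biogenesis genes rose and oocyte genes fell. Oocyte and maternal genes numbered 47, of which 2 were higher, 36 lower and 9 did not pass (2 higher and 38 lower adjusted over the list alone). Their median log2 was -2.56, with camera adjusted p = 4.92e-12 and adjusted p = 0.0214 with an estimated correlation. Among 44 ribosome biogenesis genes 31 were higher, 1 lower and 12 did not pass (31 higher and 2 lower adjusted over the list alone), with a median log2 of 2.28 (2.21 at the floor), camera adjusted p = 8.23e-09 and adjusted p = 0.0529 with an estimated correlation. With slide as a block 2732 genes passed (medians 2.04 and -2.30 for ribosome biogenesis and oocyte genes). Within slide 3 those medians were 2.29 and -2.65.

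Sets of genes, defined with groups that in part belong to these contrasts, measured the changes at scale: donor genes (1248, fibroblast over interphase zygote), activation genes (1504, cleavage-inhibited over interphase zygote) and decay genes (1500, the reverse). From M-phase zygote to 2-cell control 1244 activation genes rose and 1244 decay genes fell, and over these genes the median share of the change reached by NT embryos was compared. Prometaphase NT embryos had gone 99.8% of the activation change and 101% of the decay change. Anaphase NT embryos had gone 28.4% (13.2% in replicate 15, 41.1% in replicate 19) and 67.9% (63.4% and 68.1%). Cleavage-inhibited embryos, which defined the sets, reached 101% and 99.5%. The activation set held 32 of the 44 ribosome biogenesis genes, the decay set 31 of the 47 oocyte genes and the donor set 26 of the 31 fibroblast and 11 of the 20 macrophage genes.

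Against 2-cell controls 900 activation genes were lower and 83 higher in anaphase NT embryos (median log2 -1.46, or -1.30 with undetected genes at the floor), against 19 lower and 29 higher in prometaphase NT embryos (median 0.03). Of the decay genes 536 were higher and 83 lower after anaphase transfer (median 0.59, 0.61 at the floor), and 15 higher and 8 lower after prometaphase transfer (median -0.04). Donor genes split into 257 higher and as many lower in anaphase NT embryos, with a median of 14.8% of the fibroblast difference (3.21% in replicate 15 and 22.4% in replicate 19). In prometaphase NT embryos 34 donor genes were higher (22 without replicate 27) and the median was 2.71%, or -1.01% with undetected genes at the floor. Without prometaphase NT 27 the lower activation and higher decay counts there were 9 and 4, and without 28 they were 12 and 6. The activation count was 29 or 30 without cleavage-inhibited 20 or 38, and the decay count 8 without 2-cell control 23 and 24 without interphase zygote 1. Within slide 3 the activation medians against 2-cell controls were -1.23 for the repeat anaphase NT array and 0.03 for prometaphase NT.

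**Figure D2:**
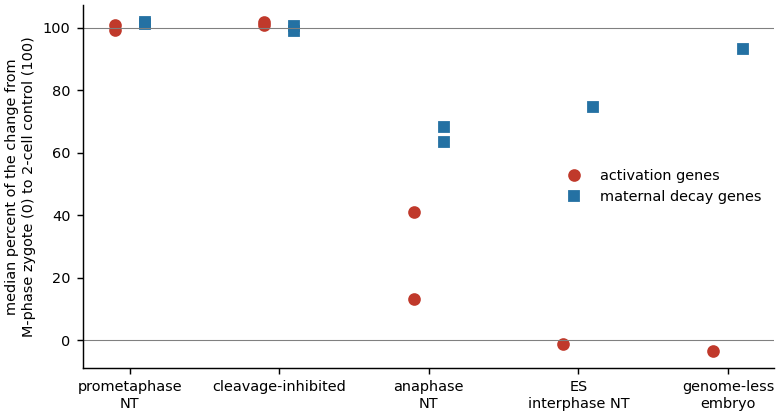
Share of the normal change from M-phase zygote (0%) to 2-cell control (100%) gone by activation and decay genes (y axis, percent, median over genes) in each sample of the groups on the x axis. Prometaphase NT samples sit near 100% for both sets, while anaphase NT samples sit at 13.2% and 41.1% for activation genes.

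Embryos kept from cleaving were set against 2-cell controls (n = 2 against 2), and 19 genes passed, 10 higher and 9 lower. Dnajc11 (log2 2.27 ± 0.39, adjusted p = 0.0278), Gtf2ird2 (at least 3.70-fold higher, adjusted p = 0.00698), the fatty acid desaturase Fads1 (log2 2.00 ± 0.30, adjusted p = 0.0105) and the chromatin remodeller Chd1 (log2 1.37 ± 0.15, adjusted p = 0.00101) were higher. Aif1l (log2 -1.82 ± 0.32, adjusted p = 0.035), the ion channel Asic1 (at least 2.10-fold lower, adjusted p = 0.00698) and Aen (at least 1.66-fold lower, adjusted p = 4.36e-06) were lower. Klf5 (log2 0.16 ± 0.53) and Nanog (log2 0.56 ± 0.95) did not pass. Camera called 0 of 25 lists, with 1 at unadjusted p under 0.05, the oxidative phosphorylation list (median log2 -0.18 or -0.17 at the floor, adjusted p = 0.0906). Fry called 0 by direction and 3 in either direction. The count was 117 without cleavage-inhibited 20, 45 without 38, 74 without 2-cell control 22 and 87 without 23. Blocked by slide it was 1, and camera then called oxidative phosphorylation (median -0.69, adjusted p = 2.5e-07) and ribosomal protein genes (-0.43, adjusted p = 0.018), both at adjusted p = 0.921 with an estimated correlation. The former list was also called without cleavage-inhibited 38 and with 75th percentile or matrix values. Its median was 0.19 without cleavage-inhibited 20, -0.57 without 38 and 0.17 within slide 3. In a fit of both groups alone or with 75th percentile scaling 0 genes passed, and 11 without background correction or with matrix values. Dnajc11 was lost without cleavage-inhibited 38 or either 2-cell control, and Aif1l without cleavage-inhibited 38 (-1.12) or 2-cell control 22.

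Between interphase and M-phase zygotes (n = 3 against 3) 220 genes changed, 138 higher and 82 lower in M phase. The oocyte homeobox gene Obox5 (log2 2.98 ± 0.52, adjusted p = 0.00828), Ciao2b (log2 2.27 ± 0.37), the HSP90 co-chaperone Ahsa1 (log2 2.25 ± 0.30), the replication origin gene Orc6 (log2 2.24 ± 0.26, adjusted p = 0.000912), Hnrnpm (log2 2.08 ± 0.42), Tcstv3 (log2 1.04 ± 0.19) and the remodeller subunit Smarcb1 (log2 1.73 ± 0.28) were higher. The histone genes H1f1 (log2 -2.92 ± 0.40, adjusted p = 0.00256) and H2bc12 (log2 -2.50 ± 0.45), the ubiquitin-conjugating enzyme Ube2c (log2 -2.33 ± 0.27, adjusted p = 0.000912), Hnrnpk (log2 -2.07 ± 0.30), the DNA methyltransferase Dnmt1 (log2 -1.37 ± 0.23) and Sall4 (log2 -1.03 ± 0.25) were lower. Camera called 0 of 25 lists, with 3 at unadjusted p under 0.05. Fry called 1 by direction, the p53 response list (2 of 18 higher and 16 not passing, median log2 0.14 or 0.08 at the floor, fry adjusted p = 0.00121). The count was 581 without interphase zygote 1, 127 without interphase zygote 31, and 142, 60 and 131 without M-phase zygotes 24, 25 and 26. Sall4, Hnrnpm, Obox5, Tcstv3 and H2bc12 were lost without M-phase zygote 25, Sall4 and Hnrnpm also without interphase zygote 30 or 31 or M-phase zygote 26, and Sall4 without M-phase zygote 24. With slide as a block it was 34, and camera then called glycolysis, ribosomal protein, pluripotency, p53 response and oocyte genes higher (medians 0.46, 0.35, 0.38, 0.18 and 0.23, adjusted p = 0.00172 to 0.029, or 0.178 and higher with an estimated correlation). The oocyte list was also called without interphase zygote 1. A fit of both groups alone called 0 genes, 75th percentile scaling 126 and matrix values 129. The p53 response median was 0.02 without M-phase zygote 26, 0.26 and 0.58 under these scalings and 0.18 within slide 4.

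Blastomere NT embryos were compared with 4-cell controls, both 14 h after transfer or release from a mitotic block (n = 2 against 2), and 201 genes passed, 148 higher and 53 lower. Genes of macrophages were among the rises: Laptm5 (log2 6.39 ± 0.63, adjusted p = 0.000675), Gpnmb (at least 125-fold higher, adjusted p = 0.00387), the complement genes C1qb (at least 6.71-fold higher, adjusted p = 0.00398) and C1qc (at least 4.52-fold higher, adjusted p = 0.00233), and lipoprotein lipase, Lpl (log2 5.71 ± 1.1). Annexins Anxa2 (log2 3.67 ± 0.46, adjusted p = 0.0034) and Anxa1 (at least 5.13-fold higher, adjusted p = 0.00719), Igfbp7 (at least 6.98-fold higher, adjusted p = 0.0336) and Cd81 (log2 6.08 ± 0.98) were higher too, with the interferon-induced Ifitm3 (log2 3.25 ± 0.71) and Ifitm2 (log2 2.76 ± 0.47). Further rises were those of Jade1 (at least 34.3-fold higher, adjusted p = 0.000675), Bbx (at least 36.1-fold higher, adjusted p = 0.0144), the p53 target Phlda3 (at least 4.75-fold higher, adjusted p = 0.0416), the paternally expressed gene Impact (log2 4.22 ± 0.46, adjusted p = 0.00117; 4-cell controls differed by -0.17 log2 from a parthenote) and the maternal gene Oosp1 (log2 1.60 ± 0.24). Lower were Cdx2, the trophectoderm homeobox gene (log2 -3.64 ± 0.51, adjusted p = 0.00515), Rhox9 (log2 -4.57 ± 1.04), Gsc (log2 -4.41 ± 0.97), and Msc (log2 -4.03 ± 0.79). Tdpoz1 (log2 -3.81 ± 0.59), Dnajc5g (log2 -3.77 ± 0.87), Spic (log2 -3.69 ± 0.66), Sox15 (log2 -2.33 ± 0.52), Dusp6 (log2 -1.88 ± 0.35) and Plk1 (log2 -1.50 ± 0.34) were also lower. Thy1 (log2 2.20 ± 0.61), Pou5f1 (log2 -1.98 ± 0.60), Nanog (log2 -1.63 ± 0.71) and Klf5 (log2 -1.47 ± 0.45) did not pass. Without blastomere NT 2 Igfbp7, Plk1 and Thy1 stood at log2 2.16, -0.96 and 0.97.

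Camera called the macrophage and fibroblast lists higher, also without any single sample, the latter not with an estimated correlation. Of 16 macrophage and leukocyte genes 6 were higher and 10 did not pass (10 higher adjusted over the list alone). The macrophage and leukocyte median was 1.55 (1.27 at the floor) log2, with camera adjusted p = 8.81e-12 and adjusted p = 0.033 with an estimated correlation. Among 19 fibroblast genes 5 were higher, 1 lower and 13 did not pass (10 higher and 2 lower adjusted over the list alone), with a median log2 of 1.76 (1.22 at the floor), camera adjusted p = 0.00193 and adjusted p = 0.248 with an estimated correlation. The fibroblast median was 3.12 without blastomere NT 1, 0.81 without 2 and 2.64 with matrix values. Without background correction it was 0.74 and the macrophage median 0.91. Camera also called the interferon and p53 response lists higher and the pluripotency list lower, on 1 or 2 passing genes each. These calls were lost with an estimated correlation and without blastomere NT 2. Of 14 interferon response and MHC class I genes 2 were higher and 12 did not pass (2 higher adjusted over the list alone). Median log2 over interferon response and MHC class I genes was 0.87 (0.57 at the floor), with camera adjusted p = 0.00231 and adjusted p = 0.248 with an estimated correlation. Among 19 p53 response genes 1 was higher and 18 did not pass (1 higher adjusted over the list alone), with a median log2 of 0.48 (0.11 at the floor), camera adjusted p = 0.00867 and adjusted p = 0.243 with an estimated correlation. Of 23 pluripotency genes 1 was lower and 22 did not pass (1 higher and 5 lower adjusted over the list alone). The pluripotency median was -0.49 (-0.36 at the floor) log2, with camera adjusted p = 0.0182 and adjusted p = 0.248 with an estimated correlation. The imprinted list was called with Impact as its only passing gene, and lost with an estimated correlation and without blastomere NT 1. Among 13 imprinted genes 1 was higher and 12 did not pass (2 higher adjusted over the list alone), with a median log2 of 0.31 (0.42 at the floor), camera adjusted p = 0.0257 and adjusted p = 0.243 with an estimated correlation. Medians of the interferon and pluripotency lists were 1.44 and -0.77 without blastomere NT 1, that of the imprinted list 0.16. Without blastomere NT 2 they were 0.10 (interferon), 0.31 (p53) and -0.18 (pluripotency), and without background correction 0.38, 0.24 and -0.27. Counts depended on single samples: 24 genes passed without 4-cell control 1, 21 without 4-cell control 2, 56 without blastomere NT 2 and 407 without blastomere NT 1. Of the 26 named calls 21 were lost without the first of these, 19 without the next, 16 without blastomere NT 2 and Dusp6 alone without blastomere NT 1. Laptm5, Jade1, Impact and C1qc were lost in none. In a fit of both groups alone or without a detection filter 130 genes passed. With slide as a block it was 20 (macrophage median 1.69, fibroblast 2.05). Within slide 7 the medians were 1.64 and 1.75.

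Oocyte NT embryos, 2 d after transfer, were first set against MII oocytes (n = 2 against 2): 3761 genes passed, 1865 higher and 1896 lower. Dppa4 (at least 544-fold higher, adjusted p = 1.31e-09), the serine synthesis enzyme Psat1 (at least 229-fold higher, adjusted p = 2.57e-08), Selenos (log2 8.85 ± 0.41), and Rabgef1 (at least 129-fold higher) rose, as did Pramel7 (at least 83.4-fold higher), Impact (at least 52.2-fold higher), nucleolin (at least 38.8-fold higher), Cdk1 (at least 30.3-fold higher) and Klf5 (log2 5.73 ± 0.45). The oocyte linker histone H1f8 (log2 -7.34 ± 0.51), Obox1 (log2 -6.90 ± 0.45), Gja4 (log2 -6.92 ± 0.51), Nrap (log2 -7.62 ± 0.66), Cmtm8 (log2 -7.48 ± 0.76), Bpgm (at least 103-fold lower), Npm2 (log2 -4.09 ± 0.54) and Gdf9 (log2 -1.52 ± 0.31) fell. Ribosome biogenesis genes rose, and oocyte genes fell. Of 43 ribosome biogenesis genes 35 were higher, 2 lower and 6 did not pass (37 higher and 2 lower adjusted over the list alone). Median log2 over ribosome biogenesis genes was 3.16 (2.76 at the floor), with camera adjusted p = 7.31e-11 and adjusted p = 0.0108 with an estimated correlation. Among 44 oocyte and maternal genes 1 was higher, 38 lower and 5 did not pass (1 higher and 39 lower adjusted over the list alone), with a median log2 of -3.11 (-2.91 at the floor), camera adjusted p = 7.31e-11 and adjusted p = 0.0117 with an estimated correlation. Both groups lay on slide 6.

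Against 4-cell controls, whose times are given on another clock, oocyte NT embryos (n = 2 against 2) differed for 796 genes, 487 higher and 309 lower. Higher genes included the maternal genes Oosp1 (log2 4.14 ± 0.24, adjusted p = 2.54e-05), Bmp15 (log2 3.93 ± 0.49, adjusted p = 0.00226), Tcl1b2 (log2 3.47 ± 0.44) and Gdf9 (log2 1.41 ± 0.31). Also higher were Bfsp1 (log2 6.29 ± 0.73, adjusted p = 0.00181), Arrdc4 (log2 5.87 ± 0.64), Cd81 (log2 5.60 ± 0.98), Gab1 (at least 18.0-fold higher, adjusted p = 0.0025), and Atp2c1 (log2 4.95 ± 0.62). Mmp2 (at least 16.7-fold higher, adjusted p = 0.00913), Laptm5 (log2 3.90 ± 0.63), Chit1 (log2 3.84 ± 0.51), and Tcstv3 (log2 3.38 ± 0.73) were higher too. Further rises were those of Tpi1 (log2 3.79 ± 0.73), cyclin G1, Ccng1 (log2 2.99 ± 0.71), Impact (log2 3.88 ± 0.46, adjusted p = 0.00182) and the Y-linked translation factor Eif2s3y (at least 14.6-fold higher, adjusted p = 0.00102), undetected in these controls and a parthenote. Lower were Nanog (log2 -4.30 ± 0.71, adjusted p = 0.00662), Pou5f1 (log2 -2.18 ± 0.60, adjusted p = 0.0422), Tbx3 (log2 -4.25 ± 1.20), and Esrrb (log2 -3.25 ± 0.58). Sox15 (log2 -2.88 ± 0.52), Id3 (log2 -2.62 ± 0.51), Gata6 (log2 -5.20 ± 1.11), Cdx2 (at least 12.7-fold lower, adjusted p = 0.00181) and Gsc (log2 -4.65 ± 0.97) were lower too. Further falls were those of Tsga8 (at least 59.7-fold lower, adjusted p = 0.0021), Sycn (log2 -5.45 ± 0.96), Rhox9 (at least 23.8-fold lower, adjusted p = 0.0149), Cldn4 (log2 -4.14 ± 0.93), Pdgfra (at least 7.09-fold lower, adjusted p = 0.00295), Ddx21 (log2 -2.01 ± 0.46) and Cox6c (log2 -1.79 ± 0.24). Klf5 did not pass (log2 -1.08 ± 0.45), and Tcstv3 stood at log2 1.87 without 4-cell control 2.

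Camera called the oocyte and maternal list higher, but not with an estimated correlation. Of 44 oocyte and maternal genes 15 were higher, 1 lower and 28 did not pass (17 higher and 1 lower adjusted over the list alone). The oocyte and maternal median was 1.07 (0.85 at the floor) log2, with camera adjusted p = 4.08e-06 and adjusted p = 0.0798 with an estimated correlation. Camera called the early zygotic activation and oxidative phosphorylation lists lower, on 4 and 5 passing genes. These calls were lost with an estimated correlation and without oocyte NT 2. Among 16 early zygotic activation genes 1 was higher, 4 lower and 11 did not pass (1 higher and 7 lower adjusted over the list alone), with a median log2 of -0.97, camera adjusted p = 0.0249 and adjusted p = 0.305 with an estimated correlation. Of 43 oxidative phosphorylation genes 5 were lower and 38 did not pass (5 lower adjusted over the list alone). Median log2 over oxidative phosphorylation genes was -0.44, with camera adjusted p = 0.00569 and adjusted p = 0.48 with an estimated correlation. The latter median was -0.25 without oocyte NT 2 and -0.78 with 75th percentile scaling, and the oocyte median 0.59 without background correction. Camera did not call the pluripotency (adjusted p = 0.0504), trophectoderm and primitive endoderm (adjusted p = 0.0544) or fibroblast lists. Of 19 fibroblast genes 2 were higher, 1 lower and 16 did not pass (3 higher and 1 lower adjusted over the list alone). The median was -0.06 (-0.22 at the floor) log2 and the mean 0.28, with camera direction up and adjusted p = 0.746. This median was 0.11 without oocyte NT 1 or 4-cell control 2. The count of genes was 81 without oocyte NT 1, 84 without 4-cell control 1 and 83 without 4-cell control 2. Of the 33 named calls 19, 17 and 19 were lost in these, among them Nanog, Pou5f1, Esrrb, Gata6, Cd81 and Mmp2 each time, and Rhox9, Tbx3 and Pou5f1 were lost without oocyte NT 2. Oosp1, Bmp15, Impact, Cdx2 and Eif2s3y were kept throughout. A fit of both groups alone called 1477, and no detection filter 497. With slide as a block 78 genes passed (oocyte list median 1.14, as within slide 6).

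**Figure D3:**
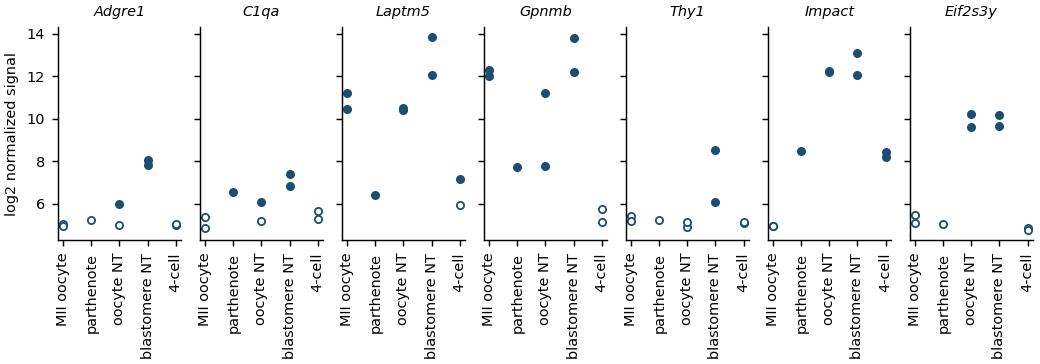
Normalized log2 signal (y axis) of genes named in the text in samples of the second array version, by group (x axis). Points are samples, open where the gene was undetected. Impact stands at 12.6 in blastomere NT, 12.2 in oocyte NT and 8.34 in 4-cell controls.

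**Figure D4:**
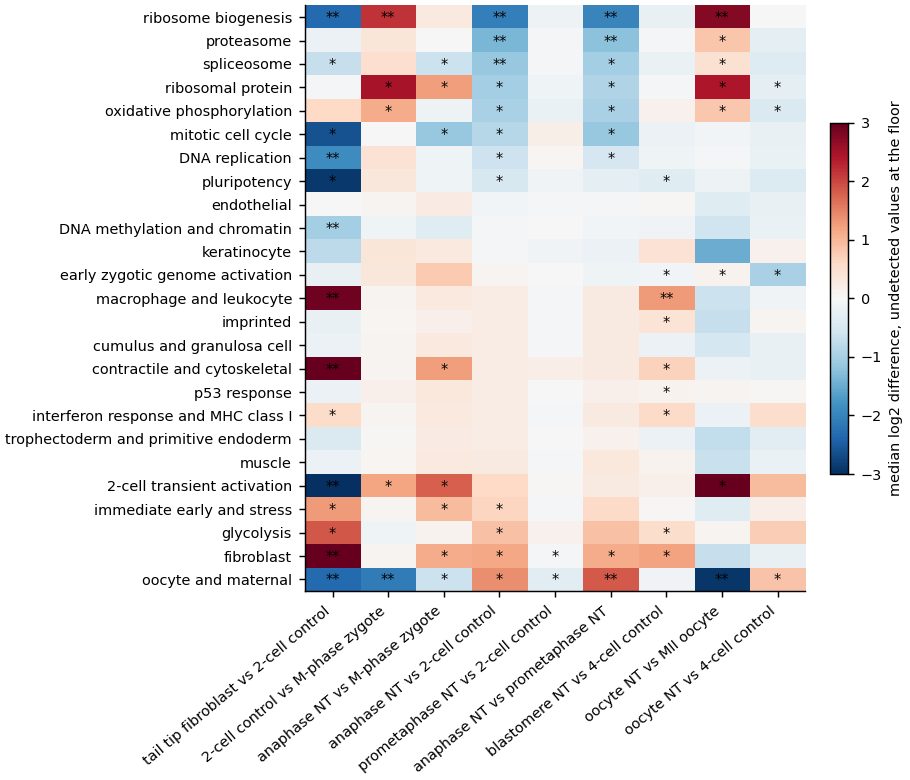
Median log2 difference (colour scale) of each of the 25 gene lists (y axis) in the comparisons on the x axis. Undetected values were set at the floor. The fibroblast list stands at 1.17 in anaphase NT and -0.02 in prometaphase NT against 2-cell controls.

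Donor genes were followed into the later transfers by symbol (1057 genes measured). Against 4-cell controls 82 were higher and 8 lower in blastomere NT embryos (median log2 0.27, 0.18 at the floor), and 60 higher and 61 lower in oocyte NT embryos (median -0.07, -0.22 at the floor). By sample the median was 0.12 in blastomere NT 1 and 3 and 0.38 in 2. The higher count in blastomere NT embryos was 13 without 4-cell control 1 or 2, 28 without blastomere NT 2 and 143 without blastomere NT 1. That in oocyte NT embryos was 10 without oocyte NT 1, 8 without 4-cell control 1 and 10 without 4-cell control 2.

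Samples with 1 array were described without a test. On the second array version, over genes that changed from MII oocyte to 2-cell control, the genome-less embryos had gone -0.264% of the activation change and 18.3% of the decay change, and ES interphase NT embryos 0.377% and 18.6%. Oocyte genes in the genome-less sample stood at a median of 2.25 (2.00 at the floor) log2 above the repeated 2-cell controls and ribosome biogenesis genes at -3.83 (-3.46 at the floor). On the first version both samples gave weak arrays (18.8 and 20.8% of probes detected), with -3.58 and -1.13% of the activation change but 93.4 and 74.7% of the decay change. The parthenote stood near the 4-cell controls (r = 0.952 across genes, which are not independent replicates), with oocyte genes 0.61 (0.39 at the floor) log2 above and oxidative phosphorylation genes at -0.49 (-0.45 at the floor).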

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

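Tests of slide, a single weak array, donor RNA and reduced transcription were chosen only after the result was seen. Anaphase and prometaphase NT embryos differed in their difference from the shared 2-cell controls for 3318 genes, tested as the direct contrast of both transfers. Blastomere and oocyte NT embryos differed in their difference from the shared 4-cell controls for 665 genes, 298 higher and 367 lower in blastomere NT. Among 5756 probes without a gene symbol, which no comparison of genes used, 1789 passed in anaphase NT embryos against 2-cell controls (853 higher and 936 lower), against 21 in cleavage-inhibited embryos.

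Activation genes stood below the 2-cell controls in anaphase NT embryos, by a median log2 of -1.46. A difference between slides as the whole cause is argued against by the median of -1.51 with slide as a block, where both replicates lay 0.43 apart, and 1 weak array by -1.23 without replicate 15. Donor RNA diluting a normal 2-cell embryo would need 63.8% of the RNA. Donor genes held less, on the linear scale a median of 3.58% of the fibroblast signal over 2-cell controls (quartiles -2.36 and 28.9%). Less transcription from the transferred genome may account for the pattern. Decay genes had gone further along their normal change than activation genes, by 50.3 percentage points in replicate 15 and 27.0 in 19. Weak signal may widen the gap in 15 (30.7% of probes detected, 38.5% in 19). A slower cell cycle and damage during transfer stay open, untested.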

How the results depend on the processing

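The fit without the weak arrays, blastomere NT 1 and 3 as separate samples, values within a slide and list tests under other settings were chosen only after the data were seen; the other alternatives were planned. Among named genes, many picked for large changes, no call reversed under any. Of their 4216 values 3830 kept direction and threshold side, 372 no longer passed, 6 newly passed and 8 uncalled values changed direction. Prometaphase NT and 2-cell controls against M-phase zygotes and oocyte NT against MII oocytes kept counts within 1.5 times under every alternative. Averaging the repeat hybridizations, slide as a random block, a log2 minimum of 1, blastomere NT 1 and 3 as separate samples and the fit without the weak arrays left the count of every comparison they applied to within that range. No paired analysis was possible, as labels pair no samples.

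With slide as a fixed block 1754 genes passed in anaphase NT and 1842 in prometaphase NT against fibroblasts, 1929 in fibroblasts against 2-cell controls, 893 in anaphase NT and 115 in prometaphase NT against 2-cell controls, 1021 between both transfers, 1948 in anaphase NT against M-phase zygotes, 1 for cleavage-inhibited embryos, 34 between zygotes, and 20 in blastomere NT and 78 in oocyte NT against 4-cell controls. A fixed block leaves fewer degrees of freedom. With the compared groups alone 353 genes passed in anaphase NT and 1 in prometaphase NT against 2-cell controls, and 890 between both transfers. Anaphase NT against M-phase zygotes gave 2137, blastomere NT 130 and oocyte NT 1477. Cleavage-inhibited embryos gave 0 (275 at unadjusted p under 0.05 in limma) and zygotes 0 (1056 unadjusted in limma). Fewer samples then estimated the spread, without other groups. Without a detection filter 130 and 497 genes passed in blastomere and oocyte NT against 4-cell controls, with more genes tested. Scaling to a 75th percentile gave 49 genes in prometaphase NT against 2-cell controls, 0 in cleavage-inhibited embryos (257 unadjusted in limma) and 126 between zygotes. Cleavage-inhibited embryos gave 11 without background correction and 11 from series matrix values, which gave 129 between zygotes. The causes of these changes of scaling and source were not tested.

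Leaving out 1 sample, with a lone sample assumed to vary like the other groups, gave 110 to 197 genes in prometaphase NT against 2-cell controls, 45 to 117 in cleavage-inhibited embryos, 60 to 581 between zygotes, 21 to 407 in blastomere NT and 81 to 742 in oocyte NT against 4-cell controls. For gene sets it gave 22 to 38 donor genes higher in prometaphase NT, with 2.02 to 3.88% of the fibroblast difference, 9 to 30 activation genes lower and 4 to 24 decay genes higher there against 2-cell controls, and 13 to 143 donor genes higher in blastomere NT and 8 to 67 in oocyte NT. The causes were not tested.

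Among the sets in anaphase NT embryos, the slide block left 90 donor genes higher, 226 activation genes higher and 360 decay genes lower than in M-phase zygotes, and 257 activation genes lower and 99 decay genes higher than in 2-cell controls. In prometaphase NT embryos it left 596 and 530 against M-phase zygotes and 6 and 4 against 2-cell controls, and in blastomere and oocyte NT 10 and 10 donor genes higher. The other set threshold, which changes the size of each set, gave 343, 564, 514 and 339 for anaphase NT (activation genes against M-phase zygotes and 2-cell controls, then decay genes), 797, 722 and 7 for prometaphase NT (activation and decay genes against M-phase zygotes, decay genes against 2-cell controls) and 97 donor genes higher in oocyte NT. In prometaphase NT against 2-cell controls 75th percentile scaling gave 15 donor genes higher, 5 activation genes lower and 6 decay genes higher, and matrix values gave 52, 10 and 32; matrix values gave 103 donor genes higher in oocyte NT. The 2.71% of the fibroblast difference held by donor genes in prometaphase NT became 4.23% without background correction, -3.42% with 75th percentile scaling, 2.59% with every probe, 2.58% with the slide block and 2.84% with the other threshold. The causes were not tested.

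Camera called 104 of 350 list tests, 35 with an estimated correlation, while fry, which compares a list with no other genes, called 183. Scaling to a 75th percentile moved the median of all genes by 0.78, 0.70 and -0.85 log2 in anaphase NT, prometaphase NT and 2-cell controls with fibroblasts, by 0.15 and -0.22 in anaphase and prometaphase NT against 2-cell controls, 0.42 between both, 0.42 and 0.31 in anaphase NT and 2-cell controls against M-phase zygotes, 0.14 between zygotes, -0.13 and -0.14 in blastomere and oocyte NT against 4-cell controls and -0.69 in oocyte NT against MII oocytes. Matrix values moved it by -0.30, -0.20, 0.25, -0.21, -0.17 and 0.49 in the contrasts of both transfers and 2-cell controls with fibroblasts, prometaphase NT and 2-cell controls with M-phase zygotes, and oocyte NT with MII oocytes. The split into higher and lower then became 4029 and 1853 (75th percentile) and 1670 and 2809 (matrix) in anaphase NT against fibroblasts, 3848 and 1650 (75th percentile) in prometaphase NT against fibroblasts, 1671 and 4257 and 2631 and 1481 in fibroblasts against 2-cell controls, 1142 and 1838 (matrix) in anaphase NT against M-phase zygotes, 9 and 2 (matrix) in cleavage-inhibited embryos, 66 and 60 (75th percentile) between zygotes, 153 and 25 (matrix) in blastomere NT, 1445 and 2898 and 2341 and 1309 in oocyte NT against MII oocytes, and 483 and 509 (75th percentile) in oocyte NT against 4-cell controls. Weak signal over background limits the genome-less and ES NT arrays of the first version. For interphase against M-phase zygotes (220 genes, highest other 43) and fibroblasts against interphase zygotes (4843, highest other 2), splits of 6 samples number 10, too few for a share under 0.05.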

Other observations

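Tests of fibroblast RNA, kept oocyte transcripts and the origin of the 4-cell controls were chosen only after the result was seen. Lists of cumulus, keratinocyte, endothelial and muscle cells and of the first lineages gave no camera call in any comparison.

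ES interphase NT embryos on the second array version stood below the repeated 2-cell controls for ribosome biogenesis genes (median log2 -3.54, -3.51 at the floor), ribosomal protein genes (-2.87), 2-cell activation genes (-3.13, -2.21 at the floor) and proteasome genes (-2.69, -2.55 at the floor), and above them for oocyte genes (2.25, 2.03 at the floor). Over the genes that changed from MII oocyte to 2-cell control, blastomere NT embryos had gone 89.3% of the activation and 99.8% of the decay change, oocyte NT embryos 92.9% and 93.7%, and the parthenote 95.0% and 97.9%. Against oocyte NT embryos the parthenote had 671 genes over 1 log2 higher and 809 lower.

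Fibroblast and macrophage lists stood above 4-cell controls in blastomere NT embryos. Fibroblast RNA present in these embryos is a candidate source: of 36 genes high in fibroblasts and undetected in 4-cell controls, 24 were detected on all 3 blastomere NT arrays and 13 on both oocyte NT arrays. Oocyte transcripts kept in the embryos were judged by detection in MII oocytes. Of genes detected in blastomere NT and not in 4-cell controls, 6 of 7 macrophage and 5 of 7 fibroblast genes were undetected there. Kept transcripts are argued against for the genes undetected there and stay open for the others. The lists were judged by unlike cutoffs, so no contrast between them is drawn. Dcn, left out as 1 of 3 arrays missed it, stood at 8.55 in MII oocytes. It was at 5.90 in blastomere NT 1 and 3 and 9.45 in 2. Whether fibroblast RNA came at 1 share for every gene cannot be told. The test (exact permutation p = 0.0598, two-sided) is void, as array versions were normalized separately. Transcription of these genes in the embryos was not tested.

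Eif2s3y, a Y-linked gene, was undetected on both 4-cell control arrays (mean 4.81), the parthenote and MII oocytes, and stood at 9.92 in blastomere NT, 9.91 in oocyte NT and 9.47 in repeated 2-cell controls. The paternally expressed genes Mkrn3 and Impact, chosen after their values were seen, were compared between 4-cell controls and the parthenote, 1 array with no spread of its own. Controls without a paternal genome could account for the lack of Eif2s3y and for the difference of Impact (-0.17 log2), but Mkrn3 was 1.68 log2 higher in the controls and detected on both of their arrays. Female embryos could account for Eif2s3y and Mkrn3, yet Impact stood at 8.34 in 4-cell controls and 9.68 in repeated 2-cell controls, so these origins cannot be told apart with 1 parthenote array. The higher Eif2s3y and Impact of NT embryos may reflect these controls rather than the transfer.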
